A study of Mus musculus with 57 samples.

How the data were processed

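Male C57BL/6 mice received a control antibody or an antibody against PAPP-A for 4 weeks, per the labels' protocols. PAPP-A (pregnancy-associated plasma protein A, encoded by Pappa) is a secreted metalloprotease that cleaves several insulin-like growth factor binding proteins and so releases insulin-like growth factor (IGF). Bone marrow was profiled unsorted (whole bone marrow, WBM) or after sorting into 6 populations: mesenchymal stromal cells (MSC), haematopoietic stem cells (HSC), common lymphoid progenitors (CLP), granulocyte-monocyte progenitors (GMP), megakaryocyte-erythroid progenitors (MEP) and Myeloid cells. The labels give each library its population, treatment, mouse pool and batch (A, B or C). The 57 libraries came from 10 control and 10 treated mouse pools, and a pool is the replicate within each population. The labels do not say how many mice a pool held. A pool number marks the same mice in every population, and control and treated pools have different numbers, so the pools pair populations and never a control with a treated library.

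Total RNA was extracted from the marrow or the sorted cells, digested with DNase I and made into strand-specific libraries with the NEBNext Ultra II Directional kit, per the labels' protocols. The authors ran FastQC 0.11.5 and Salmon, an alignment-free transcript quantifier, with the genome build mm10, per the submitters' processing notes. The Salmon version and the annotation release are not given in the sources used here. Salmon gives estimated counts, and the values deposited by the authors were expected counts per gene and library that were already whole numbers, so any rounding preceded the deposit. They were not scaled, since totals differed between libraries. The deposited table had 7385832 lines because 18072 of its genes stood on more than 1 line, with up to 62 lines for 1 gene. Repeated lines never differed (0 of 3210924 gene and sample pairs), and 1 line was kept for each gene and sample. This left 56332 genes, of which 47712 had an Ensembl gene ID and 8620 a UCSC transcript ID. A count split by Salmon between overlapping or near-identical transcripts may be uncertain for the genes concerned, and this is stated where such a gene is named. Every sample name in the table matched a label. Positions were taken from the GENCODE mouse release M21 annotation of GRCm38, matched on the Ensembl ID without its version (220 of 220 named genes matched). The release that the authors used may differ from it.

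Each treatment comparison was fitted within its population with edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr on the treatment group, libraries were scaled by trimmed mean of M-values (TMM), and the robust quasi-likelihood test was followed by Benjamini-Hochberg adjustment at 0.05. Batch was a term for MSC (A and C) and Myeloid (B and C), and the other populations came from batch A alone. CPM values use the TMM-scaled library size and are given as mean ± SD over pools, and log2 differences are treated minus control from the fit, with their standard error (SE). Adjusted p-values of single genes are from this edgeR test with Benjamini-Hochberg adjustment. A set of 43 lists of pathway genes and cell type markers was tested with camera (limma 3.58.1, preset inter-gene correlation 0.01) in each population for lists with at least 5 measured members. Camera asks whether a list's genes moved relative to all other genes, its p-values were adjusted by Benjamini-Hochberg over the lists of the population, and each was also computed with the correlation estimated from the data. Camera with the preset correlation treats the genes of a list as nearly independent. In a list test, a member counts as risen or fallen only when its own adjusted p passed the threshold.

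The difference between populations in the response was tested in 1 edgeR fit of 53 libraries with an intercept for each population and batch and a treatment effect for each population. Control MSC libraries were compared with control WBM libraries (10 libraries, with batch as a term). Each sorted population was compared with the mean of the other 5 in 1 fit of 31 control libraries with population and batch. Batch B held Myeloid controls alone, so its batch term takes them up and the level of Myeloid rests on batch C. Only MSC and WBM tie batch C to batch A. The comparisons, the lists, the alternatives first listed for them and the rule for named genes were set before the data were examined.

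The rule named, in each treatment comparison, Pappa and the members of the IGF axis, then up to 12 genes that rose and 12 that fell past the adjusted threshold with the smallest p, or all where fewer passed. Where none passed, it took the 3 genes with the smallest unadjusted p. It added the 4 members with the smallest p from each list past the camera threshold. Whatever the list test gave, it also took 4 members of the fibrillar collagen, extracellular matrix glycoprotein and marrow stromal lists in MSC, and of the neutrophil maturation and primary granule lists in GMP and Myeloid. Gene models without a usual symbol were passed over. For the control populations it named Pappa, the IGF axis and the marker list of each population. Only part of the genes that the rule covers is printed.

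Alternatives were the DESeq2 1.42.0 Wald test, relative log expression size factors, no filter beyond 1 count, a mean count of 10 or more, 1 joint fit of all populations, limma voom with sample quality weights, leaving out each pool in turn, leaving out libraries under 1/5 of their population's median total, no batch term, each batch alone, camera with an estimated correlation, fry, and the mouse pool as a block. Others were added after the data had been seen: UCSC IDs and the rRNA-like Gm42418 dropped with counts summed per symbol, pools 7 and 8 left out of MSC, pools 1 and 2 out of CLP, and pools 10 and 11 out of Myeloid. Length offsets from tximport need transcript lengths, which the table used here does not hold. The block alternative used limma voom with a correlation within pools for the joint fit and the control populations. For MSC against WBM it used edgeR with a pool term over the pools that gave both.

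The pairing of populations by mouse pool comes from the pool number in the labels. Deviations of libraries from their group and batch mean correlated with a median of 0.0254 over 63 pairs of libraries from the same pool (13 above 0.1), against -0.0085 over 180 pairs from different pools of the same treatment and batch (33 above 0.1). The consensus correlation of pools was 0.0487 in the joint fit and 0.0681 in the fit of control populations. Libraries of 1 group never agreed within sampling noise: the smallest chi-square per gene between any pair was 1.84, for the treated HSC libraries of pools 6 and 8. All 57 libraries were therefore kept as separate replicates.

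Each fit was tested on simulated counts with 200 changed genes, drawn from the real means and library sizes. Of genes changed 2-fold, the test recovered 10.5% in MSC, 35.4% in HSC, 2.06% in CLP, 38.9% in GMP, 65.7% in MEP and 15.2% in Myeloid. Of genes changed 4-fold it recovered 46.3%, 75.8%, 32.2%, 78.4%, 93.5% and 54.1% in the same order. False calls made up 10% of the calls in MSC (6 false calls), 6.14% in HSC, 6.25% in CLP, 1.74% in GMP, 5.03% in MEP and 3.23% in Myeloid, so that those of MSC, HSC, CLP and, barely, MEP exceeded the nominal 5% in this 1 simulation. These runs covered 14763, 13861, 12110, 14950, 13066 and 15500 genes. For the response of MSC minus the other populations (21525 genes), 14% of 2-fold and 34% of 4-fold changes were recovered. The comparison of MSC with WBM (17169 genes) recovered 2% and 30%, and that of control MSC with the other populations (21384 genes) 22% and 51%. Some single-gene values were not reported here.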

Results

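RNA was sequenced from 57 libraries of mouse bone marrow collected after 4 weeks of a control antibody or an antibody against PAPP-A. The mice were males aged 8 weeks. Control and treated groups held 6 and 4 MSC libraries, 3 and 4 HSC libraries, 4 and 4 libraries each of CLP, GMP and MEP, and 6 and 6 Myeloid libraries. WBM was sequenced from 4 control pools only. Batch A held the HSC, CLP, GMP and MEP libraries, 3 WBM libraries, 3 control MSC libraries and 1 treated MSC library. Batch B held 3 control and 3 treated Myeloid libraries. Batch C held 3 and 3 libraries each of MSC and Myeloid, and 1 WBM library. Single-gene p-values of the treatment comparisons within a population measure the spread between these mouse pools, each of which is 1 sample however many mice it held. Camera p-values at the preset correlation set a list's genes against the other genes and do not measure that spread. The main fits across populations had no pool term, so libraries of 1 pool counted there as separate samples.

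Total counts per library ranged from 321860 to 21812576 in MSC (median 16640136), from 107412 to 9023967 in HSC (8023673) and from 587316 to 8279964 in CLP (4116362). They ranged from 5111810 to 85017600 in GMP (17222617.5), from 6886882 to 42471152 in MEP (9150427), from 14760577 to 125537299 in Myeloid (52597739) and from 14980773 to 37113006 in WBM (35689938). The shallowest libraries were treated HSC pool 6 with 107412 counts, control MSC pool 7 with 321860 and treated MSC pool 8 with 499300. Pool 8 was the only treated MSC library of batch A.

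Pappa, the gene of the antibody's target, was a stromal transcript in control marrow. In the 6 control MSC libraries it reached 444.9 ± 103 CPM (SD, n = 6), against 0.02735 ± 0.0474 in HSC (n = 3), 0.1522 in CLP, 0.0681 in GMP, 0.2513 in MEP and 0.6968 ± 0.776 in Myeloid (n = 6). Within batch, control MSC libraries had 586.4, 560.9 and 431.3 CPM in batch A and 364.8, 360.1 and 365.7 CPM in batch C. The difference from the mean of the other sorted populations was 11.05 on the log2 scale (SE 0.382, edgeR adjusted p = 3.72e-20, higher in 6 of 6 MSC libraries). The same cells were rich in the binding proteins and ligands of the IGF axis. Igfbp4, an IGF binding protein and a known PAPP-A substrate, stood at 8598 ± 3780 CPM (log2 4.62, edgeR adjusted p = 9.49e-21). Igfbp5, another IGF binding protein, stood at 2525 ± 1380 CPM, Igfbp3 at 380.8 ± 144, the ligand Igf1 at 236.7 ± 95.8 and the ligand Igf2 at 38.48 ± 28.1 CPM (each n = 6). Of the 21 measured genes of the IGF axis list, 15 were higher in MSC and 1 was lower (16 and 1 adjusted over the list alone). The receptor gene Igf1r followed another order. It was higher in Myeloid (377.2 ± 102 CPM, log2 1.70, edgeR adjusted p = 2.66e-06) and stood at 143.7 CPM in GMP, 115.1 in HSC and 109.4 in MEP. It was lower in MSC (80.91 ± 28 CPM, log2 -0.92, adjusted p = 1.39e-05) and in CLP (60.54 CPM, log2 -1.10, adjusted p = 1.08e-04). These CPM means mix batches, and the Myeloid log2 difference rests on its 3 libraries of batch C. In WBM, Igf1r was 137.3 to 194.6 CPM in batch A and 280.3 CPM in batch C. Within batch C it was 359.3 to 519.8 CPM in Myeloid and 80.78 to 121.8 CPM in MSC.

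**Figure D1:**
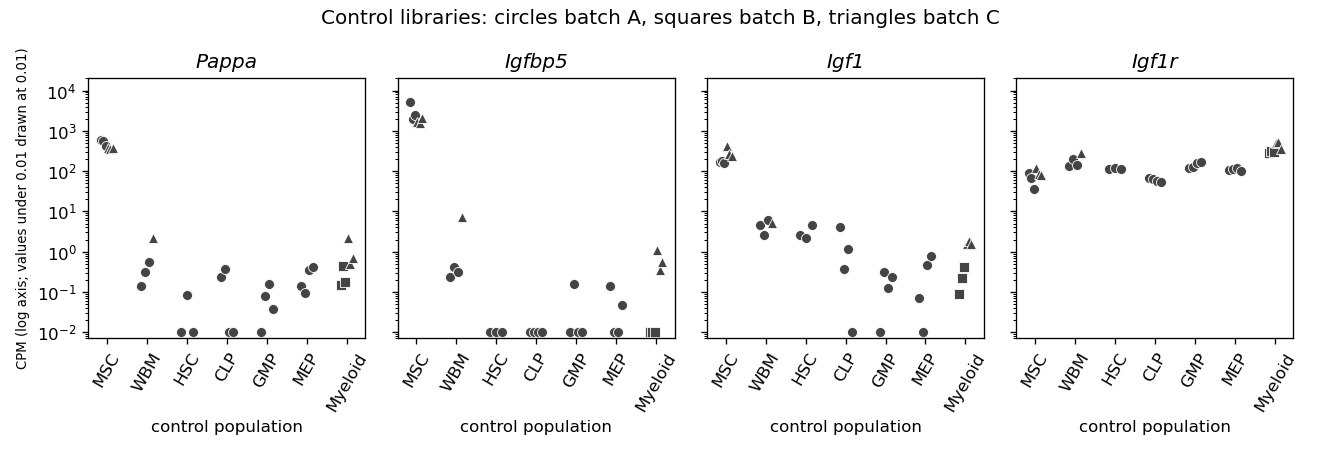
CPM of Pappa, Igfbp5, Igf1 and Igf1r in each control library of the 7 populations, on a log axis, with values under 0.01 drawn at 0.01. Pappa, Igfbp5 and Igf1 were highest in MSC, while Igf1r was highest in Myeloid, with 377.2 CPM against 80.91 CPM in MSC.

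The marker genes set for each sort were high in the population of that name. HSC libraries held the stem cell regulators Mecom at 104.6 ± 18.3 CPM (log2 7.35, edgeR adjusted p = 8.48e-10) and Hlf at 235.2 ± 35.6, and 25 of 25 stem cell genes were higher than in the other populations. CLP libraries held Dntt, the template-independent DNA polymerase of lymphocyte receptor rearrangement, at 1274 ± 319 CPM (log2 10.32, adjusted p = 3.03e-12), with 23 of 24 lymphoid progenitor genes higher. GMP libraries held Mpo, the myeloperoxidase of primary granules, at 19860 ± 3030 CPM (log2 5.39, adjusted p = 2.27e-12), with 21 of 22 progenitor and primary granule genes higher. MEP libraries held the erythroid carbonic anhydrase Car1 at 2109 ± 433 CPM (log2 7.88, adjusted p = 1.91e-08) and the erythroid transcription factor Klf1 at 185.3 ± 42.3, with 21 of 22 list genes higher (22 adjusted over the list alone). Myeloid libraries held the calcium-binding S100a9 at 43890 ± 15700 CPM (log2 9.11, adjusted p = 1.09e-07) and the granule protein Ltf at 28970 ± 5390, with 30 of 30 neutrophil maturation genes and 20 of 31 monocyte and macrophage genes higher (30 and 21 adjusted over the list alone). MSC libraries held the leptin receptor Lepr at 2973 ± 522 CPM and the chemokine Cxcl12 at 38920 ± 8780, and 33 of 33 marrow stromal genes were higher. Adjusted over the list alone, the stem cell, lymphoid, primary granule and stromal counts were 25, 23, 21 and 33. Some lists of other lineages were higher as well. HSC had 20 of 23 megakaryocyte genes higher than the mean of the other populations (median log2 3.40), against 12 of 23 in MEP (1.94). CLP had 14 of 18 dendritic cell (3.05), 11 of 19 mast cell (2.23) and 12 of 22 primary granule genes higher, and GMP 13 of 19 mast cell genes (2.50). Adjusted over the list alone these counts were 21, 13, 14, 12, 12 and 14. MSC had 10 of 12 plasma cell genes higher and 0 lower (median log2 4.38), and 8 of 23 erythroid genes higher and 2 lower (0.92). Plasma cell genes were also higher in CLP, with 6 of 12 (3.32). Adjusted over the list alone, the higher genes numbered 11, 8 and 8 in that order. Other such lists are not printed here. The log2 differences of Myeloid rest on its batch C libraries, since batch B held no other control population. The number of genes that differed from the mean of the others was 10436 in MSC (6144 higher), 3853 in HSC (2625), 2702 in CLP (1589), 4144 in GMP (2595), 5386 in MEP (3232) and 7307 in Myeloid (3046), of 21384 tested. With limma voom and the mouse pool as a block, the CLP count was 961, and the call count of every other population stayed within 1.5 times. Leaving out single pools moved the HSC, CLP and GMP counts by over 1.5 times.

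Against unsorted control marrow, Pappa, Igfbp5 and Lepr were higher in MSC and S100a8 was lower. Scaled within this comparison, Pappa stood at 385.2 ± 80.8 CPM in MSC and 0.8007 ± 0.968 in WBM (log2 9.14, edgeR adjusted p = 1.63e-07, n = 6 and 4), and Igfbp5 at 2185 and 2.04 CPM (log2 10.76, adjusted p = 6.08e-05). Lepr was 2618 CPM in MSC and 1.659 in WBM. S100a8, the partner of S100a9, fell by 4.39 on the log2 scale, from 15270 CPM in WBM to 630.7 CPM in MSC, and remained measurable in the sorted stromal libraries. No list was tested in this comparison. Igf1r was lower in MSC (71.78 against 184.8 CPM, log2 -1.48, adjusted p = 3.66e-04). In all, 8440 of 17169 genes differed (3959 higher and 4481 lower in MSC), and 5164 differed with the mouse pool as a block over the pools that gave both.

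The comparison of treated with control MSC asks how the cells that make PAPP-A respond to its blockade. Igf2 rose and Igfbp5 and Ibsp fell. Igf2 went from 34.6 ± 24.7 to 107.2 ± 35.9 CPM (SD, n = 6 and 4; log2 1.42, SE 0.234, edgeR adjusted p = 0.0435). Igfbp5 went from 2328 ± 1330 to 717.2 ± 126 CPM (log2 -1.43, SE 0.242, edgeR adjusted p = 0.0437). Ibsp, which encodes bone sialoprotein, a matrix protein of mineralising bone, went from 4342 ± 819 to 2261 ± 240 CPM (log2 -0.99, SE 0.174, edgeR adjusted p = 0.0437). Igf2 (ENSMUSG00000048583.16) lies on chromosome 7 of GRCm38 (142650766 to 142666816, minus strand), Igfbp5 (ENSMUSG00000026185.8) on chromosome 1 (72857932 to 72874884, minus strand) and Ibsp (ENSMUSG00000029306.8) on chromosome 5 (104299171 to 104311469, plus strand). The other 2 calls were transcripts with UCSC IDs, named after their values were seen. BC039192 (uc029qpa.1) fell by 1.51 on the log2 scale (4118 to 1671 CPM, adjusted p = 0.0437). CCDS26519 (uc033glq.1) had 0 counts in 6 control libraries and 11, 535, 45 and 285 counts in the 4 treated ones (adjusted p = 0.0186). Both calls are uncertain, since it was not settled which Ensembl genes they overlap or whether their reads were also counted there. Each of the 5 lay on its side in 4 of 4 treated libraries. Of 15984 genes tested these 5 passed (2 rose and 3 fell), while 676 had an unadjusted p under 0.05 and chance alone gives 799. DESeq2 called 43 genes and the fit without the low-count filter 55, each with these 5 among them. The joint fit of all populations called 649 (2 of the 5) and voom with quality weights 0. In simulated counts of these libraries, 10% of the calls were false.

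Within batch C alone (3 and 3 libraries), Igfbp5 was -1.28 (adjusted p = 0.0258), Ibsp -1.06 (0.0258) and BC039192 -1.30 (0.0142), while Igf2 at 1.10 (0.471) and CCDS26519 (0.325) did not pass. In batch A, Igf2 was 11.4 to 12.69 CPM in the controls and 62.55 CPM in the 1 treated library, and in batch C it was 53.7 to 61.39 CPM in controls and 102.1 to 149.4 CPM in treated libraries. The batch A values rest on few counts: 58, 22 and 2 in control pools 3, 5 and 7, and 34 in treated pool 8. With shallow libraries left out, Igf2 was 1.10 (edgeR adjusted p = 0.496). Without pool 8, 17, 19 or 20 no gene passed (0), and without pool 15, 5, 18 or 3 the counts were 1, 2, 2 and 3. Over 21 alternatives each, the adjusted p ran from 1.68e-05 to 0.999 for Igf2, from 8.78e-11 to 0.987 for Igfbp5 and from 4.7e-06 to 0.951 for Ibsp. Their log2 differences kept their sign, at 1.10 to 1.57, -1.70 to -1.26 and -1.06 to -0.92.

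**Figure D2:**
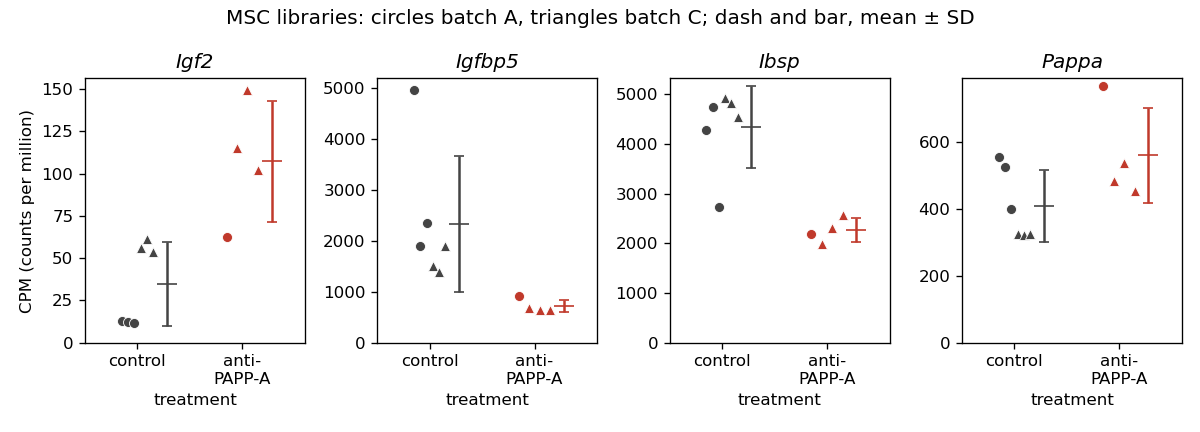
CPM of Igf2, Igfbp5, Ibsp and Pappa in each MSC library by treatment, with circles for batch A, triangles for batch C, and a dash and bar for the mean ± SD. Igf2 averaged 34.6 CPM in 6 control and 107.2 CPM in 4 treated libraries, and Igfbp5 averaged 2328 and 717.2 CPM.

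Among the other members of the IGF axis in MSC, Pappa itself was 408.8 ± 107 CPM in control and 560.8 ± 142 in treated libraries (log2 0.61, SE 0.159, edgeR adjusted p = 0.557; 0.60 in batch C alone). It did not pass in edgeR, and it passed in the DESeq2 alternative (adjusted p = 0.000465; range over 21 alternatives 0.000465 to 1). Pappa (ENSMUSG00000028370.7) lies on chromosome 4 (65124174 to 65357509, plus strand). Igfbp3 was 345.7 ± 125 and 225.3 ± 65.2 CPM (log2 -0.84, adjusted p = 0.379; -0.78 in batch C), and Igf1 was 214.9 ± 82.7 and 148.5 ± 28.2 CPM (log2 -0.65, adjusted p = 0.825; -0.81 in batch C). Each of these 3 lay on its side in 4 of 4 treated libraries. Igfbp4 was 7787 ± 3250 and 8098 ± 2510 CPM (log2 -0.17 with the batch term, adjusted p = 0.999; -0.20 in batch C). The means go the other way because control libraries had 3969 to 5509 CPM in batch A and 9451 to 11470 CPM in batch C, and 3 of 4 treated libraries were of batch C. Igf1r was 73.73 ± 24.9 and 87.4 ± 27.6 CPM (log2 0.05, adjusted p = 0.999). Of the 20 measured members 1 rose and 1 fell (2 and 3 adjusted over the list alone), and the list as a whole did not pass (median log2 -0.10, camera adjusted p = 0.426). Txnip, which encodes a glucose-responsive inhibitor of thioredoxin, was 422.2 ± 93.8 and 727.4 ± 36.4 CPM (log2 0.90, edgeR adjusted p = 0.0748; 1.02 in batch C). Igfbp3 and Txnip passed with DESeq2 (adjusted p = 0.00508 and 9.16e-06) and without the low-count filter (0.0277 and 0.00222), and Txnip in the joint fit (0.00322).

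Bone-forming genes were lower in treated MSC as a group. In the osteoblast lineage list 22 of 30 members had a negative difference and 1, Ibsp, fell. The group was lower in 3 of 4 treated libraries (3 fell adjusted over the list alone; median log2 -0.35, camera adjusted p = 0.00314; adjusted p = 0.641 with an estimated correlation). The same libraries had more neutrophil transcripts, with a median log2 difference of 0.74 for that list. Alpl, the alkaline phosphatase of mineralisation, was 204 ± 82.9 and 123.2 ± 32.9 CPM (log2 -0.90, edgeR adjusted p = 0.344). Pth1r, the parathyroid hormone receptor, was 184.6 and 145.1 CPM (log2 -0.59, adjusted p = 0.795), and Sp7, a transcription factor of osteoblasts, was 71.46 ± 17.6 and 46.94 ± 11.9 CPM (log2 -0.61, adjusted p = 0.999). Alpl and Pth1r passed with DESeq2 (0.028 and 0.0439), and Alpl without the low-count filter (0.0244). In batch C alone the list's median was -0.42 (camera adjusted p = 4.68e-06). Without pool 18 its adjusted p was 0.0522, and over 16 alternatives it ran from 4.68e-06 to 0.642. Matrix and niche genes did not pass as groups. Fibrillar collagens had a median of -0.29 (3 positive and 8 negative, camera adjusted p = 0.177), and matrix glycoproteins and proteoglycans of -0.00 (adjusted p = 0.814; 2 fell adjusted over the list alone). The marrow stromal list had a median of 0.03, a mean of -0.13 and a test in the upward direction (adjusted p = 0.216). Col5a1 was 261.1 ± 28.7 and 199.3 ± 37.9 CPM (log2 -0.47, edgeR adjusted p = 0.96), Lama2, a laminin chain, 69.85 ± 18.1 and 34.11 ± 11.6 (log2 -1.07, 0.434), and the adhesion molecule Vcam1 1887 ± 221 and 2511 ± 257 (log2 0.44, 0.96). Lama2 passed without the low-count filter (0.0395).

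Neutrophil and monocyte transcripts were higher in the same treated MSC libraries. In the neutrophil maturation list 25 of 28 members were positive (8 rose adjusted over the list alone), and the list was higher in 4 of 4 treated libraries (median log2 0.74, camera adjusted p = 2.8e-17, adjusted p = 0.362 with an estimated correlation; 0.49 in batch C alone). Ltf was 192.2 ± 95.3 and 301.7 ± 128 CPM (log2 0.87, edgeR adjusted p = 0.516), and the granule protein Ngp was 352.8 and 498.4 CPM (log2 0.74, 0.795). The monocyte and macrophage list had 16 of 23 members positive, with 2 risen and 1 fallen adjusted over the list alone (median 0.30, camera adjusted p = 0.00942, adjusted p = 0.362 with an estimated correlation, 4 of 4; 0.34 in batch C; adjusted p = 0.0932 without pool 17). Lyz2, the lysozyme of myeloid cells, was 241.9 ± 230 and 406.4 ± 430 CPM (log2 1.24, adjusted p = 0.748). Ltf, Ngp and Lyz2 passed without the low-count filter (adjusted p = 0.00832, 0.0277 and 7.6e-07). Another 8 lists, several of which mark no cell type, were higher by camera at its preset correlation. With an estimated correlation none of the 8 passed, at adjusted p = 0.362 for the stem cell list, 0.641 for the progenitor, S phase, G2/M and heat shock lists, 0.678 for the erythroid and mitochondrial lists and 0.786 for the ribosomal list. The megakaryocyte-erythroid progenitor list (median 0.55, camera adjusted p = 0.0062) was positive in 16 of 22 members, with the erythroid regulator Gata1 at 1.386 ± 1.51 and 10.37 ± 3.28 CPM (log2 2.62, adjusted p = 0.96). The erythroid list (median 0.27, 0.027) was positive in 17 of 23, with the globin gene Hbb-bt at 114.4 and 182.2 CPM. The stem cell list (median 0.13, 0.027; 2 rose adjusted over the list alone) was positive in 13 of 20, with the angiopoietin Angpt1 at 187.3 ± 29.9 and 295.6 ± 53.6 CPM (log2 0.65, 0.684). Angpt1 is also a member of the marrow stromal list. The S phase list (median 0.47, 0.00012) was positive in 26 of 32, with the replication helicase subunit Mcm3 at 16.03 and 30.5 CPM. The G2/M list (median 0.53, 9.44e-05; 1 rose adjusted over the list alone) was positive in 32 of 44, with the kinetochore motor Cenpe at 3.997 ± 1.85 and 21.71 ± 24.9 CPM (log2 2.36, adjusted p = 0.267; 0.00462 with DESeq2, 0.0245 without the low-count filter and 2.01e-06 in the joint fit). Ribosomal protein genes (median 0.14, 0.000462, 59 of 69 positive), heat shock genes (0.27, 0.0165, 14 of 17) and mitochondrially encoded transcripts (0.23, 0.027, 12 of 13) were also higher. The stem cell and mitochondrial lists were higher in 4 of 4 treated libraries, the S phase, G2/M and heat shock lists in 3, and the progenitor, erythroid and ribosomal lists in 2. In batch C alone none of these 8 lists passed. The medians there were 0.25 for the progenitor, 0.13 for the stem cell, 0.06 for the S phase and 0.20 for the G2/M list. Those of the heat shock, mitochondrial, ribosomal and erythroid lists were 0.28, 0.09, -0.09 and -0.34. Without pool 8 they did not pass either (adjusted p = 0.121 to 0.616). They also ended without pool 3 (ribosomal, mitochondrial, heat shock and erythroid), 5 (mitochondrial, stem cell and erythroid), 15 (mitochondrial, progenitor and erythroid), 17 (heat shock and stem cell), 18 (mitochondrial and stem cell), 19 (heat shock) or 20 (all but S phase, G2/M and ribosomal), at adjusted p = 0.0575 to 0.276, and over the alternatives of the 8 lists the adjusted p ran from 3.3e-11 to 0.839.

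In HSC a single gene passed. It was Pde2a, a phosphodiesterase of cyclic nucleotides, under its first ID (ENSMUSG00000030653.17): 25.85 ± 8.03 CPM in 3 control libraries and 0 in 4 of 4 treated ones (edgeR adjusted p = 0.000109). The authors' table names this ID Pde2a, whereas the GENCODE M21 annotation used for positions names it Gm45837 and gives Pde2a to the second ID only. This call is uncertain, since the position of that ID (chromosome 7, 101410886 to 101512819, plus strand) overlaps the second ID (ENSMUSG00000110195.1, 101421691 to 101512827), which went the other way, from 8.035 to 24.19 CPM (log2 1.69, adjusted p = 0.61). With counts summed per symbol, and UCSC IDs and the rRNA-like Gm42418 dropped in the same alternative, the log2 difference was -0.36 (adjusted p = 0.736; range over 15 alternatives 4.01e-29 to 0.995), and no gene passed (0). Summing adds the second ID's counts, so the treated libraries no longer stood at 0, which dropping other IDs cannot bring about. The steps were not run separately. Of 14494 genes 1156 had an unadjusted p under 0.05, where chance alone gives 725. Without pool 8 there were 149 calls, without pool 7 there were 3 and without pool 3 there were 2.

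Ribosomal protein and respiratory chain genes were higher and immediate early genes lower in treated HSC. Of 69 ribosomal protein genes 68 were positive (median log2 0.38, camera adjusted p = 1.05e-14, higher in 3 of 4 treated libraries, adjusted p = 0.987 with an estimated correlation), with Rpl10a at 600.3 ± 144 and 914.5 ± 216 CPM (n = 3 and 4; log2 0.62, edgeR adjusted p = 0.61). Of 51 nuclear genes of oxidative phosphorylation 49 were positive (median 0.51, camera adjusted p = 3.2e-14, 3 of 4, adjusted p = 0.987 with an estimated correlation), with cytochrome c, Cycs, at 63.61 ± 17.1 and 97.39 ± 6.38 CPM (log2 0.63, 0.61). Of 24 immediate early genes, which respond within minutes to growth factors and stress, 22 were negative (8 fell adjusted over the list alone; median -0.59, camera adjusted p = 1.09e-12, lower in 4 of 4, adjusted p = 0.987 with an estimated correlation). Fosb was 2051 ± 835 and 905 ± 184 CPM (log2 -1.19), Jun 1947 ± 613 and 1060 ± 229 (log2 -0.89), Klf4 209.5 ± 50.3 and 120.9 ± 31.7 (log2 -0.88) and Klf6 480.9 ± 129 and 271.8 ± 79.3 (log2 -0.78). These 4 transcription factors were lower in 4 of 4 treated libraries, with an edgeR adjusted p of 0.61 each. Fosb passed with DESeq2 (0.00713), and Fosb, Klf4, Jun and Klf6 without the low-count filter (9.17e-05, 0.0106, 0.0134 and 0.0326). The G2/M list was positive in 35 of 44 members (median 0.17, camera adjusted p = 0.00168, 3 of 4, adjusted p = 0.987 with an estimated correlation), with the centromeric histone Cenpa at 81.83 ± 15.6 and 114.8 ± 20.9 CPM. That call ended without pool 2, 5 or 8 (adjusted p = 0.0533, 0.843 and 0.514; range over 11 alternatives 5.39e-08 to 0.987), and without pool 5 its median turned to -0.0142. In the IGF axis, 9 members were measured and none passed over all genes (0 of 9; 1 rose adjusted over the list alone), and the list did not pass (median -0.26, mean -0.08, a test in the upward direction, camera adjusted p = 0.965). Socs2, a feedback inhibitor of growth hormone signalling, was 28.67 ± 12.5 and 52.87 ± 6.89 CPM (log2 0.90, edgeR adjusted p = 0.61), and Igf1r was 149.3 ± 4.35 and 177.2 ± 49.2 CPM (log2 0.28, 0.721).

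CLP showed lower immediate early genes and no called gene. Of 23 immediate early genes 21 were negative (median log2 -0.32, camera adjusted p = 9.34e-10, lower in 3 of 4 treated libraries, adjusted p = 0.809 with an estimated correlation). Fosb was 1126 ± 345 and 666.4 ± 214 CPM (n = 4 and 4; log2 -0.76) and Fos 1931 ± 311 and 1410 ± 410 CPM (log2 -0.45). Control pool 1 had the highest score of the CLP libraries (8.43) and stood apart with 14.5% rRNA-like counts. Without it the list's median was 0.00188 (adjusted p = 0.0265), and without pools 1 and 2, the highest control and the highest treated library, it was -0.36 and the call remained. Over 13 alternatives its adjusted p ran from 1.14e-13 to 0.995. The list of NF-kB targets and inflammatory cytokines was negative in 18 of 21 members (median -0.33, camera adjusted p = 0.0117, 3 of 4, adjusted p = 0.925 with an estimated correlation), with the NF-kB inhibitor Tnfaip3 at 220.2 ± 94.1 and 144.4 ± 41.6 CPM (log2 -0.61). It ended without pool 1, 4, 6 or 8 (adjusted p = 0.607, 0.117, 0.0516 and 0.259) and without pools 1 and 2 together (0.0847, median -0.0912; range over 13 alternatives 1.53e-05 to 0.995). Without pool 1 its median turned to 0.13. The megakaryocyte-erythroid progenitor list was positive in 14 of 21 (median 0.21, camera adjusted p = 0.0283, 4 of 4, adjusted p = 0.925 with an estimated correlation), with the apolipoprotein Apoe at 20.54 and 34.56 CPM (log2 0.75). It ended without pool 1, 5 or 8 (adjusted p = 0.428, 0.856 and 0.329) and without pools 1 and 2 together (0.33; range 2.59e-10 to 0.995). No gene of 12520 passed (0 by edgeR and by DESeq2), and 29 had an unadjusted p under 0.05, where chance alone gives 626. The smallest p-values belonged to Trmt1l, a paralogue of a tRNA methyltransferase (36.96 ± 6.27 and 56.37 ± 9.65 CPM, log2 0.59, edgeR adjusted p = 1), to Irs2, the adaptor of insulin and IGF receptors (32.09 ± 6.32 and 20.23 ± 2.72 CPM, log2 -0.66), and to Ap4b1, an adaptor of vesicle coats (34.34 ± 6.27 and 22.54 ± 2.14 CPM, log2 -0.59). Each lay on its side in 4 of 4 treated libraries and none passed. Igf1r was 82.86 ± 16.3 and 83.4 ± 34.9 CPM (log2 0.00), and the IGF axis list of 6 genes did not pass (camera adjusted p = 0.46).

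In GMP, genes of the neighbouring megakaryocyte-erythroid lineage were higher and no single gene passed. Of 21 progenitor genes of that lineage 20 were positive (median log2 0.48, camera adjusted p = 1.31e-08, higher in 3 of 4 treated libraries, adjusted p = 0.956 with an estimated correlation; range over 12 alternatives 3.22e-16 to 0.956). Gata2, a transcription factor of early progenitors, was 52.52 ± 16 and 74.21 ± 12.9 CPM (n = 4 and 4; log2 0.50), Apoe 54.35 ± 10.3 and 81.3 ± 14.9 (log2 0.58) and the erythroid repressor Gfi1b 2.135 ± 1.45 and 5.196 ± 3.17 (log2 1.25). Immediate early genes were negative in 16 of 24 (median -0.10, camera adjusted p = 0.000294, 3 of 4, adjusted p = 0.956 with an estimated correlation). Klf6 was 424.9 ± 76.5 and 265 ± 55.1 CPM (log2 -0.68) and Fos 1099 ± 169 and 808.4 ± 182 (log2 -0.44), whereas Myc was 217.1 ± 23.6 and 288.4 ± 14.3 (log2 0.41). That call ended without pool 1 or 4 (medians -0.0785 and -0.0682, adjusted p = 0.0646 and 0.304; range over 12 alternatives 5.04e-10 to 0.956). Control pool 1 had the highest score of the GMP libraries (7.03) and stood apart with 10.0193% rRNA-like counts. Lists of FOXO and PI3K feedback targets (median -0.06, camera adjusted p = 0.0097), mitochondrially encoded transcripts (-0.13, 0.0491) and cholesterol biosynthesis (-0.08, 0.0491) were lower, and 5 plasma cell genes at low counts were higher (0.30, 0.0317). With an estimated correlation the adjusted p of these lists was 0.647 (FOXO and plasma cell) and 0.956 (mitochondrial and cholesterol). The FOXO and plasma cell lists lay on that side in 4 of 4 treated libraries, and the mitochondrial and cholesterol lists in 3. They ended without pool 4 or 7 (FOXO), 1, 2, 6 or 7 (mitochondrial), 2, 3, 5 or 6 (cholesterol) and 1, 3, 4, 7 or 8 (plasma cell), at adjusted p = 0.0541 to 0.577. Without pool 8 the plasma cell median turned to -0.0316. Over the alternatives of these 4 lists the adjusted p ran from 0.000988 to 0.956. The neutrophil maturation list (median -0.19, adjusted p = 0.0956) and the primary granule list (-0.11, 0.0645) did not pass, with the antimicrobial Camp at 19.97 and 15.22 CPM (log2 -0.38) and the ficolin Fcnb at 53.18 ± 36 and 28.87 ± 5.41 CPM (log2 -0.85). Of 15334 genes 0 passed by edgeR or DESeq2, and 195 had an unadjusted p under 0.05, where chance alone gives 767. The smallest p-values were those of Gpcpd1, a phosphodiesterase of glycerophosphocholine (33.45 ± 3.01 and 23.89 ± 1.02 CPM, log2 -0.48, edgeR adjusted p = 1), the tetraspanin Tspan9 (10.31 ± 0.803 and 5.864 ± 0.989 CPM, log2 -0.80) and the mitochondrial nuclease Exog (20.05 ± 1.48 and 26.76 ± 1.16 CPM, log2 0.41). Each lay on its side in 4 of 4 treated libraries and none passed. The IGF axis list of 8 genes did not pass (median -0.01, mean 0.07, a test in the downward direction, camera adjusted p = 0.86), and Igf1r was 158.5 ± 16.2 and 143.3 ± 14.6 CPM (log2 -0.15).

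MEP had the most lists past the threshold (16), though 12 of 35 splits of its libraries, the real one included, gave as many or more. Immediate early genes led the MEP lists. Of 24 such genes 23 were negative (16 fell adjusted over the list alone; median log2 -0.54, camera adjusted p = 1.07e-38, lower in 4 of 4 treated libraries, adjusted p = 0.268 with an estimated correlation; range over 12 alternatives 2.12e-41 to 0.626). Klf4 was 53.75 ± 4.95 and 28.04 ± 6.71 CPM (n = 4 and 4; log2 -0.94, edgeR adjusted p = 0.54), Klf2 117.9 ± 31.3 and 57.03 ± 9.55 (log2 -1.05, adjusted p = 0.658), Fosb 1513 ± 274 and 779.9 ± 233 (log2 -0.96, 0.999) and Atf3 41.98 ± 7.12 and 26.39 ± 2.4 (log2 -0.67, 0.876). With DESeq2 these 4 passed (adjusted p = 0.000444, 0.000571, 0.00711 and 0.0193), and Klf4 also passed with voom (0.0306) and without the low-count filter (0.013). NF-kB targets and cytokines were negative in 17 of 21 (median -0.35, camera adjusted p = 8.85e-07, 3 of 4, adjusted p = 0.525 with an estimated correlation), with Tnfaip3 at 446.1 ± 93.1 and 317.2 ± 56 CPM (log2 -0.49).

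**Figure D3:**
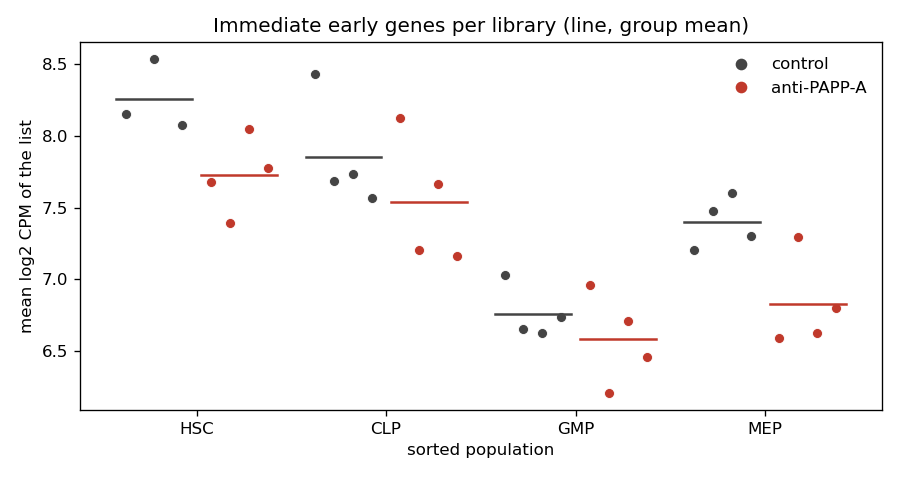
Mean log2 CPM of the immediate early gene list in each control and treated library of HSC, CLP, GMP and MEP, where a point is 1 mouse pool and a line the mean of its group. The list was lower after treatment in 4 of 4 treated libraries of HSC and MEP and in 3 of 4 of CLP and GMP.

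Within MEP, megakaryocyte genes were lower and erythroid genes higher. Of 20 megakaryocyte genes 19 were negative (median log2 -0.38, camera adjusted p = 8.85e-07, lower in 3 of 4 treated libraries, adjusted p = 0.525 with an estimated correlation), with the platelet protein Plek at 122.2 ± 38.5 and 68.7 ± 23 CPM (log2 -0.83) and the platelet chemokine Pf4 at 40.02 ± 12.8 and 24.72 ± 8.12 (log2 -0.68). Of 23 erythroid genes 22 were positive (median 0.25, camera adjusted p = 2.24e-05, 3 of 4, adjusted p = 0.525 with an estimated correlation), with the globin Hba-a2 at 45.63 ± 7.99 and 99.23 ± 68.9 CPM (log2 1.12). Heat shock genes were positive in 10 of 15 (4 rose adjusted over the list alone; median 0.12, camera adjusted p = 0.00249, 3 of 4, adjusted p = 0.525 with an estimated correlation), with the chaperones Hsph1 at 294.6 ± 35.2 and 420.8 ± 74.8 CPM (log2 0.51) and Hspa8 at 4585 ± 434 and 5649 ± 443 (log2 0.30). FOXO and PI3K feedback targets were negative in 18 of 20 (1 fell adjusted over the list alone; median -0.11, camera adjusted p = 0.000813, 3 of 4, adjusted p = 0.525 with an estimated correlation). TGF-beta targets were negative in 10 of 13 (1 fell adjusted over the list alone; -0.14, 0.00249, 3 of 4), with the inhibitory Smad7 at 42.86 ± 5.87 and 29.29 ± 4.08 CPM (log2 -0.54). With an estimated correlation neither the TGF-beta list nor any of the next 8 lists passed (adjusted p = 0.525 to 0.839). Further lists were lower: stem cell (-0.27, 0.006), dendritic cell (-0.22, 0.00867), endothelial (-0.19, 0.00374), mitochondrially encoded (-0.18, 0.0122) and cholesterol biosynthesis genes (-0.08, 0.0148). Others were higher: megakaryocyte-erythroid progenitor (0.14, 0.0181), G2/M (0.08, 0.006) and oxidative phosphorylation genes (0.07, 0.0336). Cholesterol genes lay on that side in 4 of 4 treated libraries, and the other 7 lists in 3. Single pools ended the heat shock (pool 4), TGF-beta (6), endothelial (2), cholesterol (3 or 8), dendritic cell (2, 3 or 6), stem cell (2, 3, 5 or 6), oxidative phosphorylation (2, 3, 6 or 8), mitochondrial (1, 2, 4, 6 or 7), G2/M (2, 3, 5, 6 or 8) and progenitor calls (3, 5, 6, 7 or 8), at adjusted p = 0.0539 to 0.952. The oxidative phosphorylation median turned to -0.0168 without pool 3 and -0.0234 without pool 6, and the mitochondrial median to 0.0281 without pool 7. Over the alternatives of these lists the adjusted p ran from 1.33e-13 to 0.952.

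Neutrophil transcripts were high in 1 treated MEP library. The neutrophil maturation list was positive in 21 of 24 members (median log2 1.64, camera adjusted p = 7.01e-05, adjusted p = 0.725 with an estimated correlation), but it was higher in only 2 of 4 treated libraries, and without pool 2 its median was -0.26 (adjusted p = 0.0125; range over 12 alternatives 1.19e-12 to 0.852). S100a8 was 100.2 ± 53 and 430.2 ± 671 CPM (log2 2.10), and Retnlg, a resistin-like protein of neutrophils, 2.398 ± 1.83 and 49.96 ± 95.6 CPM (log2 4.30). No gene of 13307 passed by edgeR (0), and 444 had an unadjusted p under 0.05, where chance alone gives 665. DESeq2 called 12 and voom with quality weights 2. The smallest p-values were those of Klf4 and both Pde2a IDs, at 10.26 ± 5.8 and 0 CPM for the first (edgeR adjusted p = 0.173) and 1.993 ± 0.618 and 19.01 ± 12.9 CPM for the second (log2 3.19, adjusted p = 0.54). In the IGF axis, 0 of 6 members passed over all genes and 2 rose adjusted over the list alone: Irs2 was 15.42 ± 2.61 and 21.04 ± 2.41 CPM (log2 0.44) and Socs2 0.9754 ± 0.197 and 2.194 ± 1.1 CPM (log2 1.13). The list did not pass (median 0.12, camera adjusted p = 0.0742).

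Treated Myeloid libraries had lower neutrophil, sterol and glycolytic transcripts in both batches. Of 30 neutrophil maturation genes 29 were negative, and the list was lower in 6 of 6 treated libraries (median log2 -0.28, camera adjusted p = 3.86e-05, adjusted p = 0.163 with an estimated correlation). Its medians were -0.23 in batch B (adjusted p = 0.000364) and -0.33 in batch C (0.000489). Anxa1, an anti-inflammatory lipid-binding protein, was 2289 ± 602 and 1724 ± 281 CPM (n = 6 and 6; log2 -0.41, -0.42 in batch B and -0.39 in batch C), and the neutrophil surface antigen Ly6g was 536.9 ± 83.5 and 433 ± 33.8 CPM (log2 -0.31, -0.23 and -0.37). Of 24 cholesterol biosynthesis genes 22 were negative (median -0.32, camera adjusted p = 4.3e-05, 6 of 6, adjusted p = 0.236 with an estimated correlation; -0.34 in batch B and -0.26 in batch C). Of 21 glycolysis genes 18 were negative (median -0.34, camera adjusted p = 0.00146, 6 of 6, adjusted p = 0.365 with an estimated correlation; -0.19 and -0.42). The lactate dehydrogenase Ldha was 470 ± 96.2 and 366.8 ± 48.9 CPM (log2 -0.37, -0.19 and -0.54). Interferon-stimulated genes were negative in 31 of 35 (median -0.38, camera adjusted p = 0.00305, 5 of 6, adjusted p = 0.686 with an estimated correlation). Their median was -0.31 in batch B and -0.26 in batch C, where the adjusted p was 0.225, and without pool 13 it was 0.234. Lists of primary granule genes (-0.17, 0.024, 21 of 22 negative) and p53 targets (-0.19, 0.0141, 14 of 16) were also lower (adjusted p = 0.686 and 0.365 with an estimated correlation), in 5 and 4 of 6 treated libraries. Primary granule genes had medians of 0.12 in batch B and -0.44 in batch C, and p53 targets of -0.13 and -0.34; neither list passed in batch B (adjusted p = 0.449 and 0.303). These 2 calls ended without pool 10, 14, 15, 16 or 19 (primary granule) and 9 or 12 (p53), at adjusted p = 0.0519 to 0.6. Over 19 alternatives each, the adjusted p of the interferon, primary granule and p53 lists ran from 1.44e-06 to 0.686.

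Stromal, matrix and IGF axis lists were higher in the same treated Myeloid libraries. The marrow stromal list was positive in 17 of 24 members and higher in 6 of 6 treated libraries (median log2 0.53, camera adjusted p = 0.00305, adjusted p = 0.163 with an estimated correlation). Its medians were 0.29 in batch B (adjusted p = 0.303) and 1.14 in batch C (0.000977). The stem cell factor Kitl was 0.2796 ± 0.363 and 1.091 ± 1.2 CPM. The IGF axis list was positive in 9 of 12 (median 0.27, camera adjusted p = 0.00648, 5 of 6, adjusted p = 0.163 with an estimated correlation; 0.24 in batch B and 0.29 in batch C, neither past the threshold at 0.449 and 0.0819). Pappa was 0.5511 ± 0.644 and 1.255 ± 0.958 CPM (log2 1.18, higher in 5 of 6), Igfbp5 0.2653 ± 0.354 and 0.8382 ± 0.979 (log2 2.61), and Igf1r 285.3 ± 86.5 and 310 ± 124 CPM (log2 0.09). Matrix glycoproteins (0.26, 0.0168; -0.06 in batch B and 0.97 in batch C) and matrix crosslinking genes (0.36, 0.0185; 0.19 and 0.43) were higher in 4 and 6 of 6 treated libraries (adjusted p = 0.35 and 0.163 with an estimated correlation). In batch B neither passed (0.465 and 0.418), and in batch C the glycoproteins passed (0.00466) and the crosslinking genes did not (0.128). Single pools ended the IGF axis (11 or 14), glycoprotein (11, 17 or 20) and crosslinking calls (9, 11, 12, 13 or 14), at adjusted p = 0.0554 to 0.218. Without pools 10 and 11, which had 33.9% and 24.6% rRNA-like counts, the IGF axis (median 0.13, adjusted p = 0.0547) and crosslinking calls (0.27, 0.0557) ended too, as did the heat shock call (0.24, 0.0729). Over 19 alternatives each, the adjusted p of these 3 lists and the stromal list ran from 2.38e-05 to 0.528. Dendritic cell genes were positive in 10 of 15 (median 0.37, camera adjusted p = 0.00683, 4 of 6, adjusted p = 0.364 with an estimated correlation; 0.72 in batch B and 0.41 in batch C), and the batch C value did not pass (adjusted p = 0.188), with the class II gene H2-Aa at 51.01 ± 15.5 and 82.82 ± 17.8 CPM (log2 0.74, 1.28 and 0.21). Lymphoid progenitor (0.25, 0.0412; 0.04 and 0.63) and heat shock genes (0.18, 0.0141; 0.24 and 0.09) were higher too, in 6 and 5 of 6 treated libraries (adjusted p = 0.365 and 0.163 with an estimated correlation). The lymphoid list did not pass in batch B (0.338) or with UCSC IDs dropped and symbols summed (0.0569), and the heat shock list did not in batch C (0.337). These calls ended without pool 9, 13, 14, 15, 16 or 19 and without pool 11 respectively, at adjusted p = 0.0581 to 0.194 (range over the alternatives of both 0.000352 to 0.552). Of 16803 genes 0 passed by edgeR, and 437 had an unadjusted p under 0.05, where chance alone gives 840. DESeq2 called 1 and voom with quality weights 15. The smallest p-values were those of Selenow, a small selenoprotein (23.72 ± 7.17 and 40.77 ± 14.4 CPM, log2 0.77, 6 of 6; 0.75 in batch B and 0.81 in batch C), Insm2, a zinc finger gene (0.9456 ± 0.739 and 0.04662 ± 0.0479 CPM), and Bin3, a membrane-shaping adaptor (142 ± 20.8 and 100.9 ± 21.3 CPM, log2 -0.51; -0.38 and -0.63), with an edgeR adjusted p of 0.995 each.

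Whether the response of MSC differed from that of the haematopoietic populations was tested in 1 fit over 53 libraries. That fit used 1 spread per gene for all populations, although spread differed when each was fitted alone. The biological coefficient of variation was then 0.162 in MEP, 0.449 in MSC and 0.492 in Myeloid. For treatment in MSC the joint fit called 649 genes, against 5 in the MSC fit alone. Its p-values may therefore be too small for MSC. Among the genes with a higher response in MSC were Cenpe (log2 difference 2.31, edgeR adjusted p = 5.7e-06), the mitotic gene Fam64a (4.10, 7.17e-06), the leukocyte adaptor Samsn1 (2.14, 0.000307), the immune receptor Nfam1 (2.27, 0.000374) and the leukocyte integrin Itgb2 (2.39, 0.00151). Samsn1, Nfam1 and Itgb2 are genes of leukocytes. RNA carried over from Myeloid cells, a candidate source of neutrophil transcripts in treated MSC, could raise them too, which was not tested. No list was tested in this fit. Among the genes with a lower response were the DNA helicase Pif1 (-7.07, 8.63e-05) and the redox protein Nxn (-3.22, 0.000481). Of 21525 genes 553 differed (143 higher and 410 lower), and 11 differed among the populations in any way. With limma voom and the mouse pool as a block, a change of test as well, these counts were 44 and 4. Of the 553, 294 had 0 counts in all control or all treated MSC libraries and 364 a mean MSC count under 10, and 166 of the 215 measured in the MSC fit alone had an unadjusted p under 0.05 there, of which 1 passed.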

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

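The checks in this part were chosen before their own results had been seen, but the genes examined per library were partly taken from the results. Beside Pappa they were Igf2, Igfbp5 and Ibsp, which had been called in MSC. In 44 groups of 4 to 6 values per library, 11 values stood far from the rest of their group. Chance sets apart about 1 in 20 groups that are set in advance.

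Igfbp5 was 4961 CPM in control MSC pool 3, above the other control MSC libraries, and 905.2 CPM in treated MSC pool 8, above the other treated ones. Ibsp was 2737 CPM in control MSC pool 7, below the other controls. Total counts stood apart in treated MSC pool 8 (499300), in control MEP pool 7 (42471152) and in control WBM pool 15 (14980773). The share of counts from rRNA-like genes stood apart in control MSC pool 7 (28.1%), treated Myeloid pool 10 (33.9%), control CLP pool 1 (14.5%) and control GMP pool 1 (10.0193%). The share of mitochondrially encoded transcripts was 9.14% in treated MEP pool 8.

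The treatment response differed between populations in the fit over 53 libraries: 553 genes responded differently in MSC than in the mean of the other populations, and 11 differed among the populations in any way. Chance could not be excluded for either count. Treatment was reassigned to mouse pools within batch in 24 ways, the real one included. For the first count, 2 of the 24 were as large (the highest of the others was 565), and for the second, 6 of 24 (highest 16). The reassignment with 565 calls shows that so many calls can arise under labels other than the real ones, and its cause was not tested.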

How the results depend on the processing

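The alternatives that dropped UCSC IDs and summed symbols, or left out pools 7 and 8, 1 and 2, or 10 and 11, were chosen after the data had been seen. Of 278 counts of calls under other settings, 208 stayed within 1.5 times and 70 moved. Of 768 list medians, 513 kept their sign and their side of the threshold, 239 kept their sign and lost the call, and 16 turned. Among single genes, 5109 log2 differences kept their sign and their side of the threshold, 59 lost a call and 41 gained one. Another 95 changed sign without a call in either setting. Among the treatment comparisons within a population, simulated 2-fold changes were recovered least in CLP and MSC (2.06% and 10.5%). Length offsets were not run, since no transcript lengths were given. Except where the alternative's own construction shows it (fewer libraries, or more genes tested), the cause was not tested.

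By treatment, MSC genes numbered 43 with DESeq2, 55 without the low-count filter, 649 in the joint fit (2 of the 5 shared), 0 with voom and quality weights, 3 without shallow libraries, 1 without the batch term, 3 in batch C alone, 3 with UCSC IDs dropped and symbols summed, and 2 without pools 7 and 8. HSC genes numbered 3 with DESeq2, 181 without the filter, 0 in the joint fit, 0 with voom and 0 with UCSC IDs dropped and symbols summed. MEP genes numbered 12 with DESeq2, 2 without the filter and 2 with voom. Myeloid genes numbered 1 with DESeq2, 112 without the filter, 10 in the joint fit and 15 with voom. CLP and GMP had 0 under every alternative run. With an estimated correlation and with fry, 0 lists passed in MSC, HSC, CLP, GMP, MEP and Myeloid. Without pools 1 and 2, CLP had 10 lists, but of the 3 called with them the NF-kB (adjusted p = 0.0847) and progenitor lists (0.33) ended. Relative log expression size factors, a mean count of 10 and, in Myeloid, leaving out pools 10 and 11 moved none of these counts by over 1.5 times. Leaving out pools 10 and 11 still ended the Myeloid IGF axis (0.0547), crosslinking (0.0557) and heat shock calls (0.0729).

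Leaving out 1 pool at a time gave 0 to 4 genes in MSC (3 without pool 3, 2 without 5 or 18, 1 without 15, 0 without 8, 17, 19 or 20), 1 to 149 in HSC (2 without pool 3, 3 without 7, 149 without 8) and 0 to 1 in MEP (1 without pool 3). CLP, GMP and Myeloid stayed at 0. Lists numbered 7 to 18 in MSC (7 without pool 8 or 20, 18 without 16), 3 to 5 in HSC, 3 to 11 in CLP (8 without pool 1, 11 without 2, 6 without 3, 7 or 8), 3 to 12 in GMP (12 without pool 3, 3 without 6), 14 to 18 in MEP and 11 to 17 in Myeloid. Control HSC genes numbered 1857 to 4989 (2261 without pool 3, 1857 without 5, 2505 without 7), CLP 1408 to 3137 (1408 without pool 1, 1771 without 3, 1549 without 5, 1710 without 7) and GMP 2276 to 5598 (2276 without pool 5, 2523 without 7).

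With the mouse pool as a replicate block, the response of MSC minus the others gave 44 genes, any difference 4, MSC against WBM 5164 and control CLP 961. These alternatives changed no other count of calls by over 1.5 times. They also replaced edgeR by limma voom or, for MSC against WBM, kept only the pools that gave both. The falls in counts therefore cannot be credited to the block alone. Within a population no pool has both treatments, so no paired fit of treatment exists there. Without the filter, the response of MSC minus the others gave 274.

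List medians that turned were those of MSC ribosomal (-0.0915 in batch C alone, -0.0834 without pools 7 and 8, -0.0909 to 0.23 over single pools, negative without pool 8), MSC erythroid (-0.34, -0.33 and -0.34 to 0.61, negative without pool 8), HSC G2/M (-0.0142 to 0.41, negative without pool 5), CLP NF-kB (-0.75 to 0.13, positive without pool 1), CLP immediate early (-0.63 to 0.00188, the latter without pool 1), GMP plasma cell (-0.0316 to 0.41, negative without pool 8), MEP oxidative phosphorylation (-0.0234 to 0.18, negative without pool 3 or 6), MEP mitochondrial (-0.45 to 0.0281, positive without pool 7) and MEP neutrophil genes (-0.26 to 2.02, -0.26 without pool 2). In batch B alone, Myeloid matrix glycoproteins were at -0.0593 and primary granule genes at 0.12.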

Other observations

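The tests of batch A alone, of batch C alone, of a chance difference in immediate early genes and of stromal RNA in Myeloid libraries were chosen after their results or the pattern they bear on had been seen. The tests of Myeloid RNA in MSC and of handling of the pools, and the regroupings of samples, were not.

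Other fates of stromal cells were also profiled by lists, and none of them passed in treated MSC. The adipogenic list had 12 of 20 members positive (median log2 0.16, camera adjusted p = 0.177), the chondrocyte list 3 of 12 (median -0.29, 0.871) and the fibroblast and periosteal list 18 of 24 (median 0.14, 0.0647). Collagens outside the fibrillar group were negative in 15 of 23 (median -0.35, 0.0602), and endothelial genes were positive in 9 of 18 (median -0.00, 0.961). No member passed over all genes or adjusted over the list alone (0 each). The genes next named were chosen after their values were seen: the adipokine Adipoq was 1375 ± 485 and 1252 ± 366 CPM in control and treated MSC (n = 6 and 4; log2 -0.36), the lipoprotein lipase Lpl 1927 ± 997 and 2954 ± 1140 (log2 0.47), and the microfibrillar collagen Col6a3 105 ± 44.5 and 57.58 ± 20.7 (log2 -1.09), with an edgeR adjusted p of 0.999, 0.999 and 0.825. Immediate early genes, lower in the progenitor populations, were positive in 11 of 24 in MSC (median -0.02, camera adjusted p = 0.961).

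The overlapping Pde2a IDs differed in opposite directions in HSC and MEP. The first ID had 0 CPM in 4 of 4 treated libraries of HSC, MEP and MSC. In control libraries it had 17.95 to 37.01 CPM in HSC, 6.534 to 19.63 CPM in MEP and 0 in 5 of 6 MSC libraries (12.52 CPM in pool 17). The second ID was 5.161 to 14.18 CPM in control and 17.15 to 35.56 CPM in treated HSC, 1.162 to 2.519 and 7.243 to 37.24 CPM in MEP, and 24.86 to 100.7 and 122.2 to 160.9 CPM in MSC. In GMP, treated libraries had 13.06 to 22.69 CPM for the first ID and controls 0 to 14.3 CPM. The cause was not tested.

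In treated MSC the osteoblast list was lower while neutrophil transcripts were higher. Dilution of stromal RNA by Myeloid RNA is too small to carry the lower osteoblast list. The share of Myeloid RNA computed from the counts went from 1.51% to 2.13%, which gives 2.6% of the list's median change. The shares are plain means over libraries, and batch A held 3 control MSC libraries and 1 treated one. They therefore mix batch with treatment, whereas the list's median is from the fit with a batch term, so the 2.6% is approximate. Shares of RNA from other haematopoietic cells were not computed, so dilution by those stays open. Batch A alone is argued against as well, since the osteoblast median was -0.42 within batch C. A candidate source of the neutrophil transcripts is RNA carried over from Myeloid cells. The 48 genes specific to Myeloid cells and outside the lists had a median of 0.803 in MSC, within the quartiles of the neutrophil list (0.529 and 1.05). They were picked for low values outside Myeloid in the control libraries, the control MSC ones included. Such a choice favours a rise in treated MSC, so this value does not settle the source. A response of osteoblast-lineage cells to the antibody, or a change in which stromal cells were sorted, stays open as an untested hypothesis found in these data.

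Immediate early genes were lower in treated HSC, CLP, GMP and MEP, which shared their mouse pools except that HSC had no library of pool 1. Handling that varied from pool to pool could lower them, and it cannot be told apart from treatment here: the pools' deviations correlated between populations with a mean of -0.0681 (permutation p = 0.587 upper and 0.413 lower), and 4 pools a group are too few. The pools' mean scores were 0.394, 0.133, 0.265 and 0.0612 in controls and -0.0185, -0.333, -0.0959 and -0.308 after treatment, an exact permutation p of 0.02857, the smallest that 4 against 4 allows. The score of 0.394 is that of pool 1, whose CLP and GMP libraries stood apart in rRNA-like counts. Without pool 1 the CLP median was 0.00188, whereas without pools 1 and 2 it was -0.36 and the call remained. The GMP median was -0.0958 with pool 1 and -0.0785 without it, and the MEP score of pool 1 (7.206) was the lowest of the MEP controls. Whether RNA quality in that pool contributed was not tested. Chance stays possible, because a difference as large relative to its spread arose for any of 36 lists in 8 of 35 splits of the pools, a share of 0.229. A response to the antibody stays open and untested.

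Stromal and matrix transcripts were higher in treated Myeloid libraries. RNA from stromal cells may be their source: 39 genes specific to MSC and outside the lists had a median of 0.575 there, within the quartiles of the stromal list (-0.107 and 1.01). That check is weak. The genes were picked for low values outside MSC in the control libraries, the control Myeloid ones included, which favours a rise in treated Myeloid. The quartiles also enclose 0, so any positive median up to 1.01 would have passed. Whether batch C alone is the cause stays open: the stromal median was 0.2913 in batch B (adjusted p = 0.303) and 1.14 in batch C, and matrix glycoproteins were at -0.0593 in batch B. A sort that lets more stromal fragments through and expression by Myeloid cells stay open as hypotheses.

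For the counts of genes called by treatment in MSC and HSC, chance could not be excluded. Splits of the same libraries into groups of the same sizes within batch gave as many calls in 4 of 80 for MSC (real 5, highest other 45) and 8 of 35 for HSC (1; 623). The real count was 0 in CLP, GMP, MEP and Myeloid, so every split is as large by construction and the splits say nothing about chance there. Their highest other counts were 1, 9, 1776 and, in 100 splits drawn from 200, 100. Splits that call 623 or 1776 genes point to structure among the samples other than treatment. For the counts of lists, the splits as large were 39 of 80 in MSC (11; 21), 32 of 35 in HSC (4; 15), 35 of 35 in CLP (3; 19), 23 of 35 in GMP (6; 19), 12 of 35 in MEP (16; 22) and 13 of 100 in Myeloid (13; 17), and chance could not be excluded for these either. It could be excluded for control MSC against WBM (8440; 375), where 1 of 80 splits, the real one, was as large. The same held for each control population against the others, with 1 of 40 reassignments each: MSC (10436; 3606), HSC (3853; 1629), CLP (2702; 85), GMP (4144; 1109), MEP (5386; 1466) and Myeloid (7307; 4584).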
